A study of Mus musculus with 16 samples.

How the data were processed

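Small RNA libraries came from fragments of mouse blastocysts cut apart with a laser into a polar piece, which contains the inner cell mass, and a mural piece of trophectoderm. Per the labels, adapters with unique molecular identifiers were ligated, 12 to 20 PCR cycles were run, no size selection was made, and reads of 75 nt were taken on an Illumina NextSeq500. The deposited values are counts, as whole numbers of reads or molecules per mature miRNA name, without normalization. Genome build GRCm38 is named in the submitters' processing notes. The aligner, the counting tool, the miRNA annotation version and whether reads with the same identifier were collapsed are not given in the sources used here. Intervals and floors below therefore cover counting error only. All 16 libraries listed the same 1978 names.

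Libraries were grouped by the tissue and treatment labels into 6 groups: polar and mural fragments of WT blastocysts (n = 2 libraries each), of blastocysts diapaused in vivo (n = 3 each) and of blastocysts treated with an mTOR inhibitor, called mTORi (n = 3 each). The titles of the 3 mural mTORi libraries name no part and hold both mTORi and the word diapaused. The tissue and treatment labels and the column headers place them as mural and mTOR-inhibited, and they were used so. The labels do not say whether a polar and a mural fragment with the same replicate number came from the same embryos, or how many embryos each library holds. The p-values therefore measure the spread between these samples. Stage and treatment cannot be separated, because WT blastocysts were taken at embryonic day 4.5 and diapaused ones at EDG 7.5. No embryonic day is given for the mTORi libraries, so comparisons with them cannot separate age from the inhibitor either. No library batch is labelled.

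Counts were analysed in R 4.3.3 with edgeR 4.0.16. Names were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 102 tested miRNAs holding 92.83% to 97.61% of the counts of each library. TMM factors scaled the libraries. A quasi-likelihood model with a mean for each group was fitted over all 16 libraries, with 10 residual degrees of freedom, a common dispersion of 0.1417 (a coefficient of variation of 0.376) and 7.13 prior degrees of freedom. There were 14 contrasts: each treatment against WT in each part and averaged over the parts, polar against mural in each treatment and averaged, diapaused against mTORi in each part, and the difference of each treatment effect between the parts. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over the tested miRNAs of a contrast with the two-sided edgeR test. Levels are tested counts after TMM scaling to a library of 1000000 (CPM), and a prior count of 2 was used for logarithms. Where a group had no count, the bound on the fold was taken from 3 counts over the group, and with 1 to 3 counts the ratio of counts is given with its exact 95% interval.

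Lists of miRNAs, 27 in number, were fixed before the data were examined, as were the contrasts, the test and the rule for named miRNAs. They were the clusters miR-290/miR-295, miR-302/miR-367, miR-17/miR-92 with its paralogs, miR-183/miR-96/miR-182, miR-221/miR-222, miR-23/miR-27/miR-24, miR-322/miR-503, the Sfmbt2 cluster and the Dlk1-Dio3 cluster. The families were miR-200, let-7, miR-15/miR-16, miR-26, miR-29, miR-30, miR-34/miR-449, miR-148/miR-152, miR-181, and miR-99/miR-100 with miR-125. For other cell types, lists of erythroid, leukocyte, endothelial, muscle, liver, stromal, neural and stratified epithelial miRNAs were used. Lists with at least 3 tested members, of which there were 10, were tested in 7 contrasts with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 70 tests. The same tests were run with an estimated correlation and with fry. Shares are percentages of all miRNA counts of a library, given as mean and SD per group without a test, since 2 against 3 libraries cannot reach p 0.05 in an exact permutation test.

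The named miRNAs were the 10 with the largest rise and the 10 with the largest fall in each treatment contrast against WT within a part, and 5 and 5 in the other contrasts. They had to be called, to average at least 10 CPM and to have no overlap between the libraries of the groups compared. The overlap condition was not used for the differences between parts. Where fewer than 5 were called, the 5 with the smallest p were added as values. The 10 miRNAs with the highest mean CPM and up to 4 members of each discussed list were also named. A list was discussed if camera called it or at least 3 members were called, and the lists of other cell types were always given. Any other name was chosen after its values were seen, and the text says so. Precursor positions came from the GRCm38 annotation, in which 1901 of the names had a position and 81 had 2 or more precursors.

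Alternatives set beforehand were DESeq2 size factors (called RLE), library size alone, no filter, a filter on a mean of at least 10 CPM, the Wald test of DESeq2 1.42.0, a fit of only the groups compared, a block for the replicate number, and leaving out each library in turn. Chosen after seeing the data were thinning of every library to 1744 counts (median of 21 draws) and a fit without the miR-290/miR-295 cluster. Where leaving out a WT library leaves 1, that library is assumed to vary like the other groups. Statements that a miRNA was called in each left-out fit cover only the miRNAs named by the rule. The overlap of the 2 treatments, which share WT libraries, was set beside 100 simulations of unchanged groups.

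The fit was tested on simulated data with 20 sets of 102 miRNAs, in which known changes were placed. A 4-fold change was recovered in 57.5% of cases for diapaused against WT in polar fragments, 50.5% for mTORi in polar, 64.5% for diapaused in mural and 61.0% for mTORi in mural fragments. Averages over parts recovered 88.5% and 84.5%, and the differences between parts 26.5% and 22.5%. No simulated change was called with the wrong sign, and 3.8% to 6.4% of calls were false. Every library was drawn independently with the fitted dispersion, so outlying libraries and links between same-numbered libraries were not simulated. The recovered and false shares do not cover such cases. A 4-fold rise of the miR-200 family was called by camera in 20 of 20 sets. Its members were drawn independently there and tested at the preset correlation of 0.01, while their estimated correlation in the data was 0.322. The sets therefore do not show how camera behaves with correlated members.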

Results

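Small RNA was sequenced from 16 libraries of mouse blastocyst fragments, with 122251 miRNA counts in all. Polar fragments hold the inner cell mass, and mural fragments hold the trophectoderm on the far side of the cavity. Each part was taken from normal (WT) blastocysts at embryonic day 4.5 (n = 2 libraries), from blastocysts diapaused in vivo at EDG 7.5 (n = 3) and from blastocysts treated with an mTOR inhibitor (mTORi, n = 3). Diapause is a reversible arrest of the blastocyst before implantation, and mTOR is a kinase that couples nutrients to growth. The series asks how miRNA levels differ when blastocysts pause naturally or through mTOR inhibition.

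The total count per library ran from 1744 (polar WT replicate 1) to 20051 (mural diapaused replicate 2), an 11.5-fold range. Totals were 1744 to 4940 in polar WT, 9049 to 14500 in polar diapaused and 2184 to 3501 in polar mTORi libraries. In mural fragments they were 6435 to 8366 for WT, 12607 to 20051 for diapaused and 3490 to 4386 for mTORi. No count was recorded in any library for 1481 of 1978 mature names, and 140 to 296 names were detected per library. A group count of 0 allows up to 448.8 CPM in polar WT and 63.2 CPM in mural diapaused, the shallowest and deepest groups. Replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 1.995 to 21.671. The highest value was between polar mTORi replicates 1 and 3.

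The miR-290/miR-295 cluster, the main miRNA cluster of mouse embryonic stem cells, gave the largest share of the counts of any list. It held 52.98% ± 3.32 (SD, n = 2) in polar WT, 42.6% ± 4.01 (n = 3) in polar diapaused and 37.6% ± 8.50 (n = 3) in polar mTORi libraries. The polar mTORi mean was lowered by replicate 3 at 27.88%, with 41.13% and 43.73% in the others. In mural fragments it held 50.6% ± 0.574 (SD, n = 2) in WT, 49.8% ± 1.10 (n = 3) in diapaused and 41.2% ± 1.19 (n = 3) in mTORi libraries. The 10 miRNAs with the highest mean level were miR-292a-5p, miR-294-3p, miR-10b-5p, miR-293-3p, miR-292a-3p, miR-200c-3p, miR-182-5p, miR-203-3p, miR-148a-3p and miR-200b-3p. Of the 1292 counts of miR-203-3p, 748 were in polar mTORi replicate 3, and without that library its mean fell from 22022 to 5725.7 CPM and its rank from 8 to 36. The miR-302/miR-367 cluster, known from the epiblast, held 0.401% and 0.162% of the counts of the polar WT libraries (15 counts) and 0.0210% to 0.0884% of those of the polar diapaused libraries (15 counts). In polar mTORi libraries it had 2 counts, both in replicate 2. In mural fragments it had 0 counts, which allows shares of up to 0.0203% (WT), 0.00632% (diapaused) and 0.0261% (mTORi).

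Polar and mural fragments were compared to ask which miRNAs mark each part. The miR-322/miR-503 cluster, an X-linked cluster known for restraint of the cell cycle, was higher in mural fragments, at 7.52% ± 0.269 (SD, n = 2) of counts in mural WT against 0.646% ± 0.346 (n = 2) in polar WT libraries. The Dlk1-Dio3 cluster, imprinted and expressed from the maternal copy of chromosome 12, was higher in polar fragments, with 98, 372 and 81 counts in polar WT, diapaused and mTORi libraries against 5, 3 and 4 in the mural ones. miR-152-3p was higher in polar fragments of diapaused blastocysts, at 2780.3 ± 1024 CPM (SD, n = 3) against 130.2 ± 34.2 (n = 3). miR-148a-3p was 2.55-fold higher in polar than in mural WT fragments (log2 1.35, SE 0.29, edgeR adjusted p = 0.00632).

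All 5 tested members of the miR-322/miR-503 cluster were called lower in polar fragments of WT and of diapaused blastocysts, and 1 of 5 in mTORi. The counts were also 5, 5 and 1 when adjusted over the list alone. In WT, miR-322-5p (chromosome X, 53054255 to 53054349) was at 1548.5 ± 722 CPM (SD, n = 2) in polar and 19802 ± 1958 (n = 2) in mural fragments, a log2 difference of -3.54 (SE 0.62, edgeR adjusted p = 0.00231). miR-351-5p differed by -3.24 (SE 0.64), miR-503-5p by -3.68 (SE 0.91) and miR-322-3p by -2.41 (SE 0.72). miR-503-3p had a count ratio of 0.0454 (95% interval 0.00113 to 0.265). Averaged over treatments, camera placed the cluster lower in polar fragments (adjusted p = 0.000432, and adjusted p = 0.097 with an estimated correlation). In library size scaling, 4 members in WT and 2 in diapaused blastocysts were called lower.

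Of the 4 tested members of the Dlk1-Dio3 cluster, 2 were called higher in polar WT fragments, 3 in diapaused and 1 in mTORi. The counts were 4, 4 and 3 when adjusted over the list alone. miR-379-5p (chromosome 12, 109709060 to 109709125) had no count in any mural library. It was at least 7.99-fold higher in polar fragments of WT, at least 21.9-fold in diapaused and at least 11.8-fold in mTORi blastocysts. miR-541-5p was at least 8.72-fold higher in polar WT fragments, and its count ratio in diapaused ones was 79.7 (95% interval 13.9 to 3190.0). miR-409-3p, in an intron of Mirg as miR-541-5p is, was at least 8.26-fold higher in polar diapaused fragments. Averaged over treatments, all 4 members were called, with miR-127-3p at an edgeR adjusted p = 0.00199. Camera called the cluster (adjusted p = 0.00187, and adjusted p = 0.149 with an estimated correlation).

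**Figure D1:**
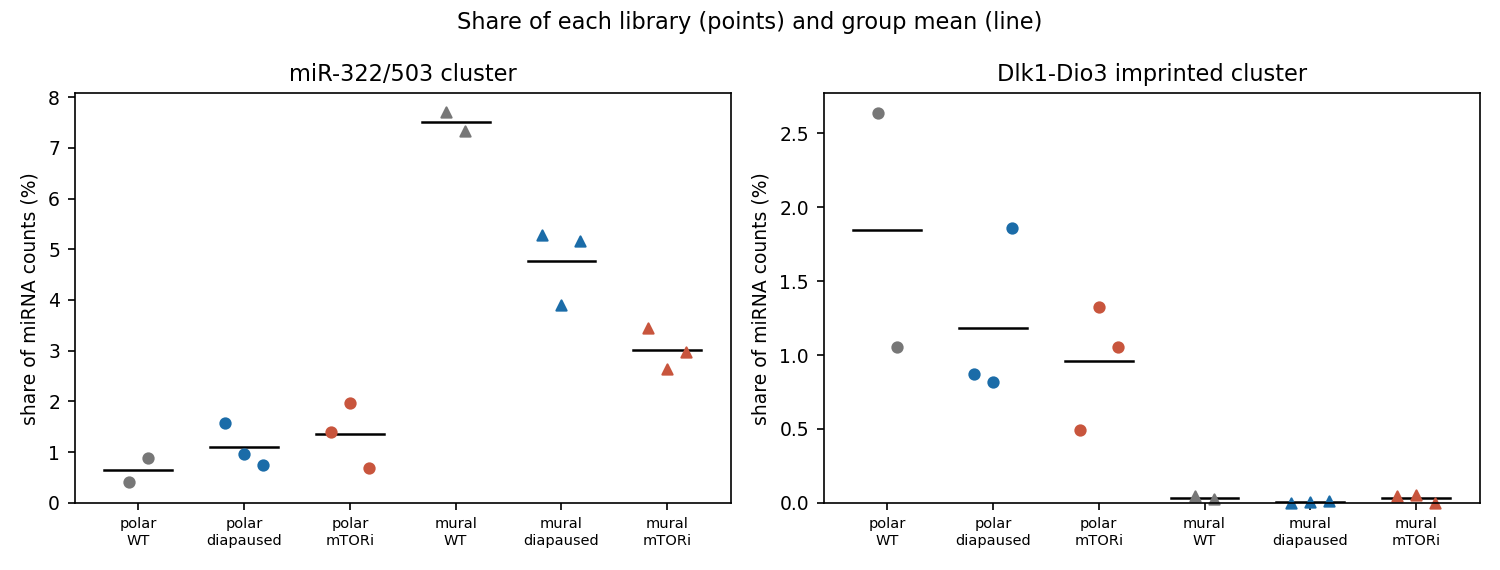
Share of miRNA counts (%) of the miR-322/miR-503 cluster (left) and the Dlk1-Dio3 cluster (right) in each of the 16 libraries (points), with the mean of each group as a line. The miR-322/miR-503 cluster averaged 7.52% in mural WT and 0.646% in polar WT libraries, and the Dlk1-Dio3 cluster 0.0353% and 1.85%.

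Other miRNAs also differed between the parts. miR-10b-5p (chromosome 2, 74726070 to 74726137, in an intron of Hoxd4) was lower in polar fragments by a log2 difference of -2.12 (SE 0.44) in WT, -1.17 (SE 0.33) in diapaused and -1.21 (SE 0.34) in mTORi blastocysts. miR-152-3p had a log2 difference of 4.23 (SE 0.67) in diapaused blastocysts and was at least 5.0-fold higher in polar mTORi fragments. miR-5099 was also higher in polar diapaused fragments (log2 1.63, SE 0.53), and miR-10a-5p was lower (log2 -1.87, SE 0.57). Mural diapaused replicate 2 held 306 of the 383 counts of miR-10a-5p in its group, and without it the difference was -0.52 (SE 0.44, edgeR adjusted p = 0.48). Averaged over treatments, miR-672-5p was higher in polar fragments (log2 1.81, SE 0.42) and miR-378a-3p (log2 -1.01, SE 0.24) and miR-30d-5p (log2 -0.73, SE 0.19) were lower. Of the miR-17/miR-92 cluster and its paralogs, linked to proliferation, 3 of 6 tested members were higher in polar fragments on average (3 adjusted over the list alone), miR-92a-3p by 0.89 (SE 0.22), miR-25-3p by 0.88 (SE 0.27) and miR-93-5p by 0.84 (SE 0.28). Of the miR-200 family, known for the epithelial state, 3 of 5 were lower in polar fragments on average (3 adjusted over the list alone), among them miR-200b-3p by -0.94 (SE 0.20).

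Members of the miR-290/miR-295 cluster were lower in polar than in mural fragments of diapaused blastocysts, with 4 of 13 called (4 adjusted over the list alone). They were miR-294-3p (log2 -0.77, SE 0.15), miR-292a-5p (log2 -0.70, SE 0.17), miR-292a-3p (log2 -0.70, SE 0.20) and miR-293-5p (log2 -0.93, SE 0.29). With library size scaling 0 were called and the median of the 13 was -0.13 in place of -0.58. Averaged over treatments, 3 members were called lower (1 adjusted over the list alone), the median was -0.16, and it was 0.00 with library size scaling. Among polar WT libraries, replicate 2 held 113 of the 115 counts of miR-451a, the main red blood cell miRNA, and erythroid miRNAs took 1.27% ± 1.64 (SD, n = 2) there against 0.102% ± 0.0093 (n = 2) in mural WT.

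Polar against mural gave 11 calls in WT (4 higher and 7 lower), 19 in diapaused (5 and 14), 5 in mTORi (3 and 2) and 28 averaged over treatments (13 and 15). A fit of only the groups compared called fewer in WT and in mTORi and more in diapaused blastocysts, as given below. With library size scaling the split was 13 higher and 2 lower (86.7% higher in place of 26.3%) in diapaused, 3 and 1 in mTORi (75% in place of 60%) and 16 and 9 on average (64.0% in place of 46.4%). The 5 mTORi calls include miR-203-3p, chosen after its values were seen, whose log2 difference of 3.50 became 0.20 (SE 0.45, edgeR adjusted p = 0.919) without polar mTORi replicate 3. The call of miR-451a in WT (log2 3.63), also chosen after its values were seen, became -0.20 (SE 1.49, edgeR adjusted p = 0.983) without polar WT replicate 2. Leaving out a library gave 4 to 8 calls in WT, with 4 without mural WT replicate 1, 6 without polar WT replicate 1 and 7 without mural WT replicate 2, and miR-322-5p and miR-351-5p were called in each fit. In diapaused fragments it gave 5 to 11 (5, 7 and 10 without polar replicates 3, 2 and 1, and 8, 11 and 8 without mural replicates 1, 2 and 3), and in mTORi 3 without polar replicate 3 and 0 in edgeR without any 1 mural replicate (16, 21 and 22 at unadjusted p under 0.05).

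Diapaused and WT blastocysts were compared to ask how natural pausing changes miRNA levels. In polar fragments, miR-10b-5p rose 4.15-fold, from 8780.5 ± 2142 CPM (SD, n = 2) to 37209 ± 9899 (n = 3). miR-200c-3p rose 2.40-fold, from 21256 ± 4437 CPM (SD, n = 2) to 50655 ± 3896 (n = 3), and miR-148a-3p rose 1.88-fold, from 14579.7 ± 1401 to 27341 ± 1679. miR-672-5p (chromosome X, 104116175 to 104116274, in an intron of Nexmif) fell from 14575.5 ± 61.1 CPM (SD, n = 2) to 2685 ± 315.5 (n = 3). In mural fragments, miR-148a-3p rose 3.26-fold, from 5674 ± 93.5 CPM (SD, n = 2) to 18544 ± 1983 (n = 3), and let-7d-5p rose 7.60-fold, from 491 ± 187 to 3752 ± 792.

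In polar fragments, 8 of 102 miRNAs were called, 6 higher and 2 lower (6 and 7 with RLE factors, 46.2% higher in place of 75%). Log2 changes were 2.05 for miR-10b-5p (SE 0.42, edgeR adjusted p = 0.00653), 1.26 for miR-200c-3p (SE 0.25, adjusted p = 0.00653), 1.47 for miR-30d-5p (SE 0.37), 1.39 for miR-200b-3p (SE 0.38) and 0.91 for miR-148a-3p (SE 0.26, adjusted p = 0.0379). miR-152-3p (chromosome 11, 96850393 to 96850465, in an intron of Copz2) had a count ratio of 17.8 (95% interval 3.11 to 710.0). The log2 change of miR-672-5p was -2.43 (SE 0.55, edgeR adjusted p = 0.00885). The fall of miR-451a, chosen after its values were seen, was -4.07 and became -0.44 (SE 1.46, edgeR adjusted p = 0.943) without polar WT replicate 2, where miR-672-5p was at -2.38 (adjusted p = 0.069). Leaving out a library gave 2 calls without polar diapaused replicate 2 and 4 without replicate 1 or 3, and miR-10b-5p and miR-200c-3p were called in each fit.

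In the miR-200 family, 2 of 5 members rose in polar diapaused fragments (4 adjusted over the list alone), with a median log2 change of 1.71. Camera called the family (adjusted p = 0.0144, and adjusted p = 0.354 with an estimated correlation). The family held 8.59% ± 0.310 (SD, n = 3) of the counts in polar diapaused and 3.17% ± 0.135 (n = 2) in polar WT libraries. In the miR-148/miR-152 family, which shares a seed sequence, 2 of 3 members rose (3 adjusted over the list alone), and camera called it (adjusted p = 0.0382, and adjusted p = 0.231 with an estimated correlation). With RLE factors that camera call was lost (adjusted p = 0.0543). The member not called, miR-148b-3p, had a log2 change of 1.33 (SE 0.59).

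In mural fragments, 10 miRNAs were called, 8 higher and 2 lower (3 and 2 with either other scaling, 60% higher in place of 80.0%). miR-148a-3p (chromosome 6, 51269812 to 51269910, intergenic) had a log2 change of 1.71 (SE 0.27, edgeR adjusted p = 0.000793). Changes were 1.73 for miR-30d-5p (SE 0.35), 2.93 for let-7d-5p (SE 0.65), 2.91 for miR-30b-5p (SE 0.87), 2.87 for miR-23a-3p (SE 0.82), 1.79 for miR-25-3p (SE 0.49), 0.93 for miR-200c-3p (SE 0.24) and 0.60 for miR-294-3p (SE 0.17). The falls of miR-5126 (log2 -5.65) and of miR-2137 (log2 -3.17, chosen after its values were seen) became -1.0 (SE 1.16, edgeR adjusted p = 0.794) and -0.20 (SE 1.27, adjusted p = 0.955) without mural WT replicate 2, which held 207 counts of miR-5126. Without that library edgeR called 0 miRNAs (10 at unadjusted p under 0.05), with miR-148a-3p at 1.65 (SE 0.42, adjusted p = 0.105). The count was 5 without mural WT replicate 1, and 4, 6 and 4 without diapaused replicates 1, 2 and 3.

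Averaged over the parts, 19 miRNAs were called in diapaused blastocysts, 15 higher and 4 lower (11 and 5 with RLE factors, 68.8% higher in place of 78.9%). Of the 4 falls, 3 rest on 1 WT library. Without mural WT replicate 2, miR-5126 went from -4.23 to -1.84 (edgeR adjusted p = 0.133) and miR-2137, chosen after its values were seen, from -2.84 to -1.29 (adjusted p = 0.381). Without polar WT replicate 2, miR-451a, also chosen so, went from -2.54 to -0.78 (adjusted p = 0.75). In the miR-200 family 4 of 5 members rose (5 adjusted over the list alone, 3 of 5 over all miRNAs with RLE factors), including miR-141-3p (log2 1.85, SE 0.53) and miR-200a-3p (log2 1.28, SE 0.38). In the let-7 family, known to increase with differentiation, 3 of 5 members rose (3 adjusted over the list alone, 2 over all miRNAs with either other scaling). They were let-7d-5p (log2 2.58, SE 0.47), let-7g-5p (log2 1.24, SE 0.31) and let-7i-5p (log2 1.81, SE 0.62). Several names with 2 or more precursors, among them let-7f-5p, miR-16-5p, miR-26a-5p and miR-24-3p, had at most 6 counts in any library (miR-92a-3p, with 713 counts in all, and miR-466f-3p, with 191, did not follow this), so that the let-7, miR-15/miR-16, miR-26 and miR-23/miR-27/miR-24 lists rest on their other members. The same holds for miR-181a-5p, miR-29b-3p and miR-125b-5p, with 0 counts in all, and miR-30c-5p, with 1, in the lists of their families. miR-30b-5p (log2 2.61, SE 0.76) and miR-10a-5p (log2 2.26, SE 0.60, and 1.60 with an edgeR adjusted p = 0.0176 without mural diapaused replicate 2) rose, and miR-672-5p fell (log2 -2.05, SE 0.39, edgeR adjusted p = 0.000933). Only 7 of the 19 called miRNAs, those named by the rule, were checked in every left-out fit. The calls with the smallest p, miR-148a-3p, miR-30d-5p and miR-200c-3p, were not among them. Leaving out a library gave 7 calls without mural WT replicate 2, 9 and 12 without polar WT replicates 2 and 1, and 12 without mural diapaused replicate 2, and let-7d-5p and miR-672-5p were called in every fit.

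**Figure D2:**
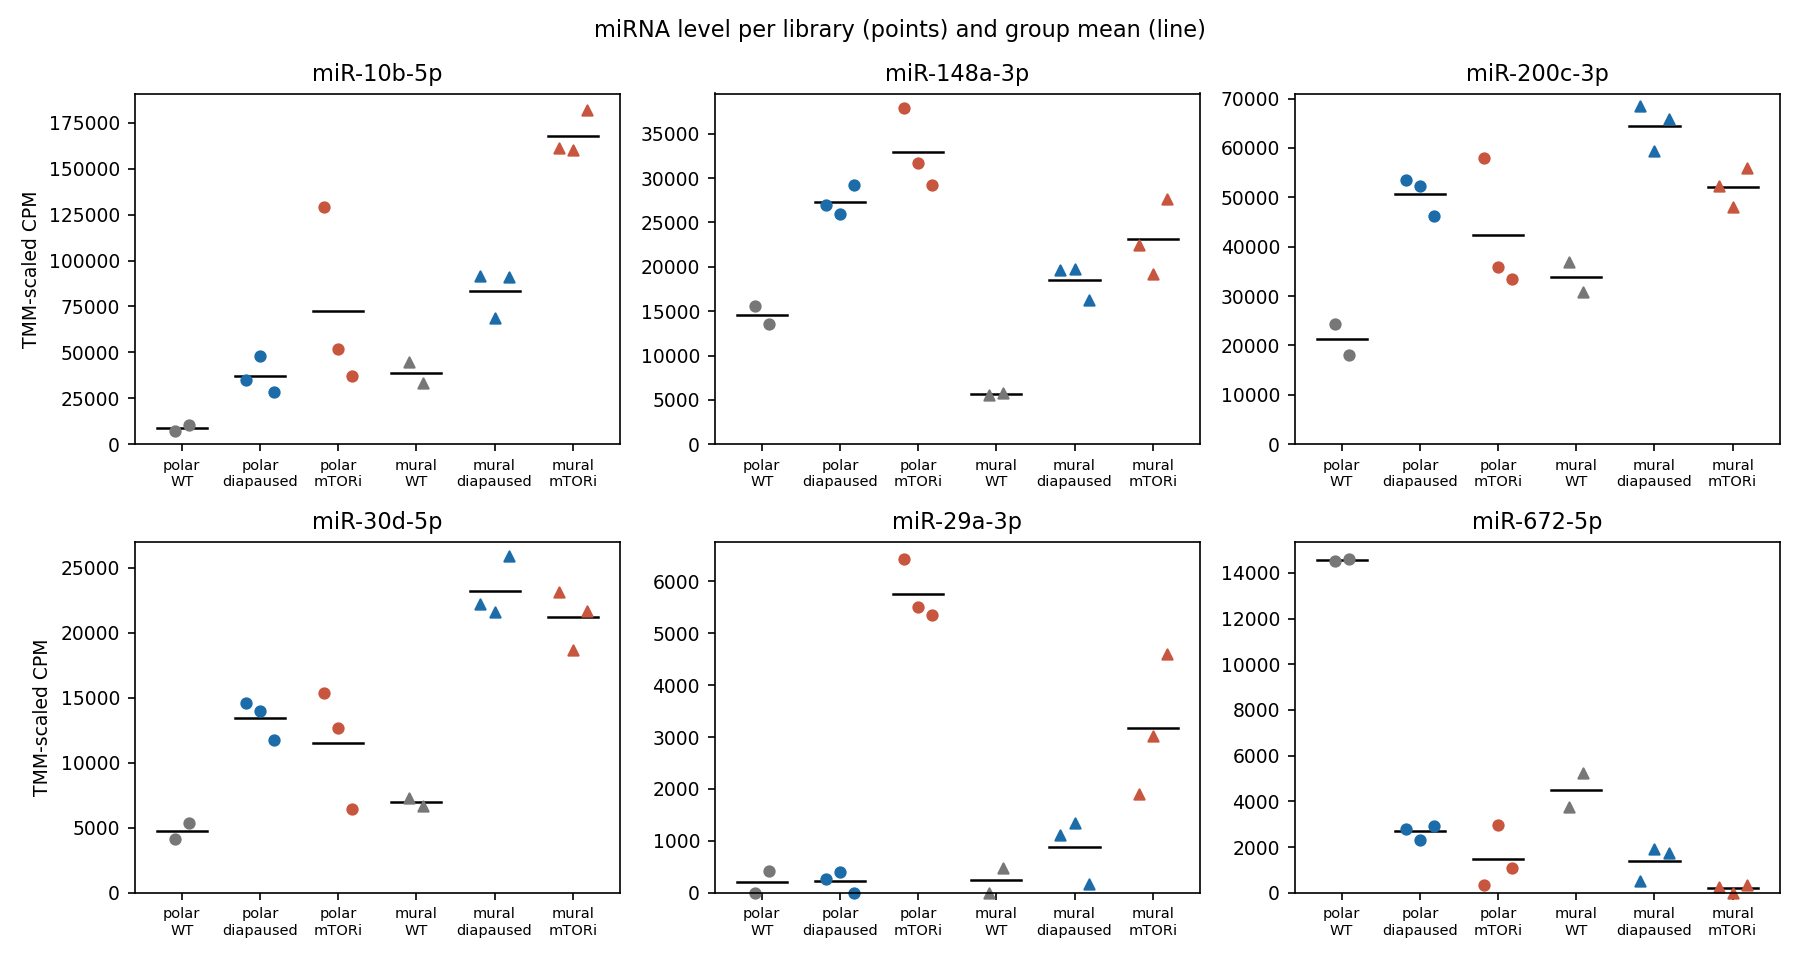
TMM-scaled CPM of 6 miRNAs in each of the 16 libraries (points), with the mean of each group as a line. miR-148a-3p averaged 5674 CPM in mural WT, 18544 in mural diapaused and 23090.4 in mural mTORi libraries, and miR-672-5p was highest in polar WT at 14575.5 CPM.

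Blastocysts treated with the mTOR inhibitor were compared with WT to ask what induced pausing changes. In polar fragments, miR-10b-5p rose 8.10-fold, from 8780.5 ± 2142 CPM (SD, n = 2) to 72588 ± 49494 (n = 3). miR-29a-3p, known to target collagen and DNA methyltransferase transcripts, was at 5760 ± 592 CPM (SD, n = 3) against 205.9 ± 291.2 (n = 2), a count ratio of 19.6 (95% interval 5.12 to 167.0). miR-672-5p fell from 14575.5 ± 61.1 CPM (SD, n = 2) to 1462 ± 1345 (n = 3), and miR-292a-5p fell from 234960.1 ± 20338 to 153126 ± 39333, a fall not called without polar mTORi replicate 3 (log2 -0.21 in place of -0.62, edgeR adjusted p = 0.479). In mural fragments, miR-10b-5p rose 4.31-fold, from 39020 ± 7827 CPM (SD, n = 2) to 167939.6 ± 12323 (n = 3), and miR-148a-3p rose 4.05-fold. miR-351-5p and miR-503-5p of the miR-322/miR-503 cluster fell there, from 16994 ± 862 to 1782 ± 474 CPM and from 27917 ± 265 to 2565 ± 972 CPM.

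In polar fragments, 23 miRNAs were called, 13 higher and 10 lower (11 and 15 with library size scaling, 42.3% higher in place of 56.5%). A fit of only the groups compared called far fewer, as given below. The log2 change of miR-10b-5p was 3.02 (SE 0.44, edgeR adjusted p = 0.000257). Count ratios were 13.1 (95% interval 4.20 to 65.6) for miR-23a-3p and 8.23 (95% interval 2.55 to 42.2) for miR-10a-5p. Further rises were 2.04 for miR-322-5p (SE 0.60), 1.90 for miR-148b-3p (SE 0.61), 1.53 for miR-200b-3p (SE 0.39), 1.46 for miR-26b-5p (SE 0.41), 1.24 for miR-30d-5p (SE 0.38), 1.18 for miR-148a-3p (SE 0.27) and 1.01 for miR-200c-3p (SE 0.25). Without polar mTORi replicate 2 the rise of miR-322-5p was 1.22 (edgeR adjusted p = 0.137), and without replicate 1 that of miR-10b-5p was 2.29. Falls were -3.35 for miR-672-5p (SE 0.64, edgeR adjusted p = 0.00339), -2.60 for miR-17-5p (SE 0.74), -1.79 for miR-93-5p (SE 0.51), -1.31 for miR-291a-5p (SE 0.41), -0.95 for miR-182-5p (SE 0.31) and -0.62 for miR-292a-5p (SE 0.19). miR-340-5p had no count in polar mTORi libraries and was at least 7.83-fold lower than in WT. Count ratios were 0.0568 (95% interval 0.00135 to 0.369) for miR-186-5p and 0.160 (95% interval 0.0298 to 0.558) for miR-466f-3p, a name with 4 precursors whose source is uncertain.

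The stratified epithelial miRNAs miR-203-3p (log2 4.61, SE 1.19) and miR-205-5p (log2 4.24, SE 1.34) were also called higher, and they moved with 1 library. Their share was 25.8% in polar mTORi replicate 3, and 0.719% to 1.83% in the other polar mTORi libraries. Without replicate 3 the change of miR-203-3p was 1.52 (SE 0.54, edgeR adjusted p = 0.063) and that of miR-205-5p was 1.54 (SE 1.01, adjusted p = 0.27). That fit gave 13 calls, and miR-23a-3p (log2 2.61, adjusted p = 0.0608), miR-93-5p (log2 -1.62, adjusted p = 0.0701) and miR-292a-5p (log2 -0.21, adjusted p = 0.479) were not among them. Nor were miR-17-5p (log2 -1.75, edgeR adjusted p = 0.0812), miR-182-5p (log2 -0.45, adjusted p = 0.256), miR-291a-5p (log2 -0.72, adjusted p = 0.214) and miR-466f-3p (log2 -1.74 in place of -2.56, adjusted p = 0.101). miR-340-5p also lost its call (edgeR adjusted p = 0.063), though it had 0 counts in all 3 polar mTORi libraries, so its difference from WT does not rest on replicate 3. The fall of miR-451a (log2 -3.64, chosen after its values were seen) became 0.11 (SE 1.53, edgeR adjusted p = 0.973) without polar WT replicate 2. The count was 7 without polar WT replicate 1 and 4 without replicate 2, and miR-10b-5p and miR-672-5p were called in every fit.

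**Figure D3:**
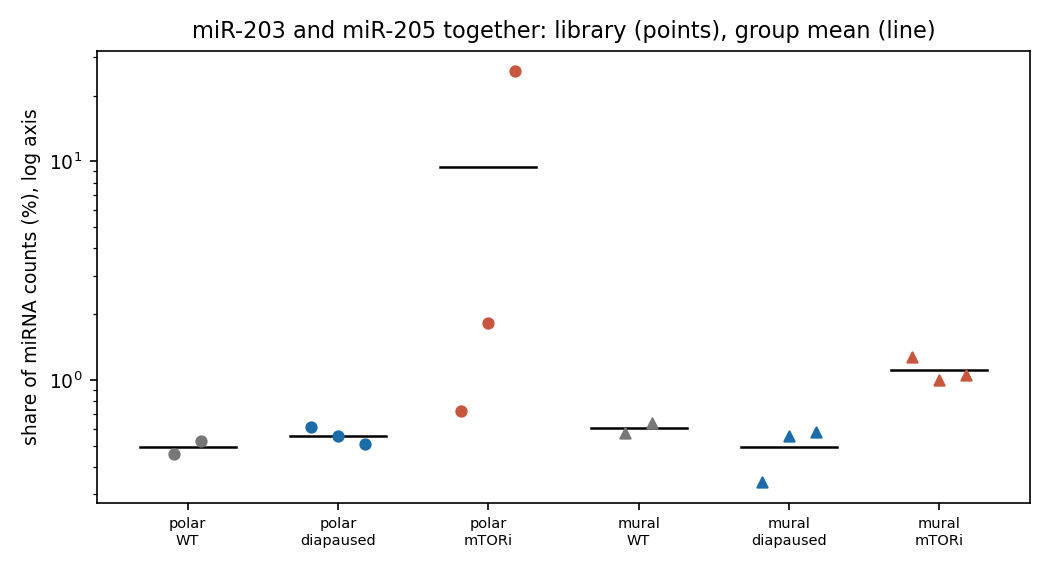
Share of miRNA counts (%, log axis) of miR-203 and miR-205 together in each of the 16 libraries (points), with the mean of each group as a line. Polar mTORi replicate 3 stands at 25.8%, and the WT libraries reach 0.634%.

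In mural fragments, 12 miRNAs were called, 6 higher and 6 lower (4 and 7 with RLE factors, 36.4% higher in place of 50%). A fit of only the groups compared called more here and fewer in polar fragments, as given below. Which part has more mTORi calls thus depends on the setting. Rises were 3.49 for miR-29a-3p (SE 1.01), 2.85 for miR-23a-3p (SE 0.86), 2.11 for miR-10b-5p (SE 0.40, edgeR adjusted p = 0.00152), 2.02 for miR-148a-3p (SE 0.28, adjusted p = 0.00012), 1.59 for miR-30d-5p (SE 0.35) and 1.53 for miR-26b-5p (SE 0.40). Falls were -3.41 for miR-503-5p (SE 0.75), -3.26 for miR-351-5p (SE 0.55, edgeR adjusted p = 0.000755), -2.36 for miR-466f-3p (SE 0.61), -2.13 for miR-99b-5p (SE 0.60) and -1.58 for miR-290a-5p (SE 0.43). miR-672-5p had a count ratio of 0.0400 (95% interval 0.00475 to 0.150). Leaving out a library gave 6 calls without mural mTORi replicate 3 or mural WT replicate 1 and 7 without mural WT replicate 2. miR-10b-5p, miR-148a-3p, miR-672-5p and miR-351-5p were called in each fit.

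Averaged over the parts, 33 miRNAs were called in mTORi blastocysts, 16 higher and 17 lower (11 and 19 with library size scaling, 36.7% higher in place of 48.5%). Fewer were called in a fit of only the groups compared, as given below. Rises included miR-29a-3p (log2 3.88, SE 0.77), miR-23a-3p (log2 3.18, SE 0.65), miR-10b-5p (log2 2.56, SE 0.30), miR-30b-5p (log2 2.61, SE 0.82, and 1.80 with an edgeR adjusted p = 0.107 without polar mTORi replicate 2) and miR-203-3p (log2 2.87, SE 0.78, and 1.40 with an edgeR adjusted p = 0.00705 without polar mTORi replicate 3). Falls included miR-672-5p (log2 -3.92, SE 0.53), miR-1981-5p (edgeR adjusted p = 0.0391), miR-298-5p (log2 -2.82, SE 0.77) and miR-466f-3p (log2 -2.46, SE 0.47). In the miR-290/miR-295 cluster 3 of 13 members fell (3 adjusted over the list alone): miR-290a-5p (log2 -1.32, SE 0.30), miR-291a-5p (log2 -1.01, SE 0.28) and miR-292a-5p (log2 -0.51, SE 0.13). In the miR-17/miR-92 cluster and its paralogs miR-25-3p rose (log2 1.11, SE 0.37) and miR-93-5p (log2 -1.58, SE 0.36) and miR-17-5p (log2 -1.65, SE 0.53) fell. In the miR-322/miR-503 cluster miR-322-5p rose (log2 1.06, SE 0.38; not called with library size scaling) and miR-351-5p (log2 -1.45, SE 0.43) and miR-503-5p (log2 -1.78, SE 0.60) fell, also 1 and 2 when adjusted over the list alone. In the part where it was not called, miR-322-5p was at 0.07 (SE 0.45, mural), miR-351-5p at 0.35 (SE 0.66, polar) and miR-503-5p at -0.14 (SE 0.93, polar, and -2.46 without polar mTORi replicate 1). The differences between the parts were not called for these 3 (edgeR adjusted p = 0.27, 0.0651 and 0.27). The count was 12 without polar WT replicate 2 and 20 without mural WT replicate 1. Without polar mTORi replicate 3, miR-292a-5p was at -0.23 (adjusted p = 0.207), miR-291a-5p at -0.62 (adjusted p = 0.071) and miR-17-5p at -1.13 (adjusted p = 0.0867).

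**Figure D4:**
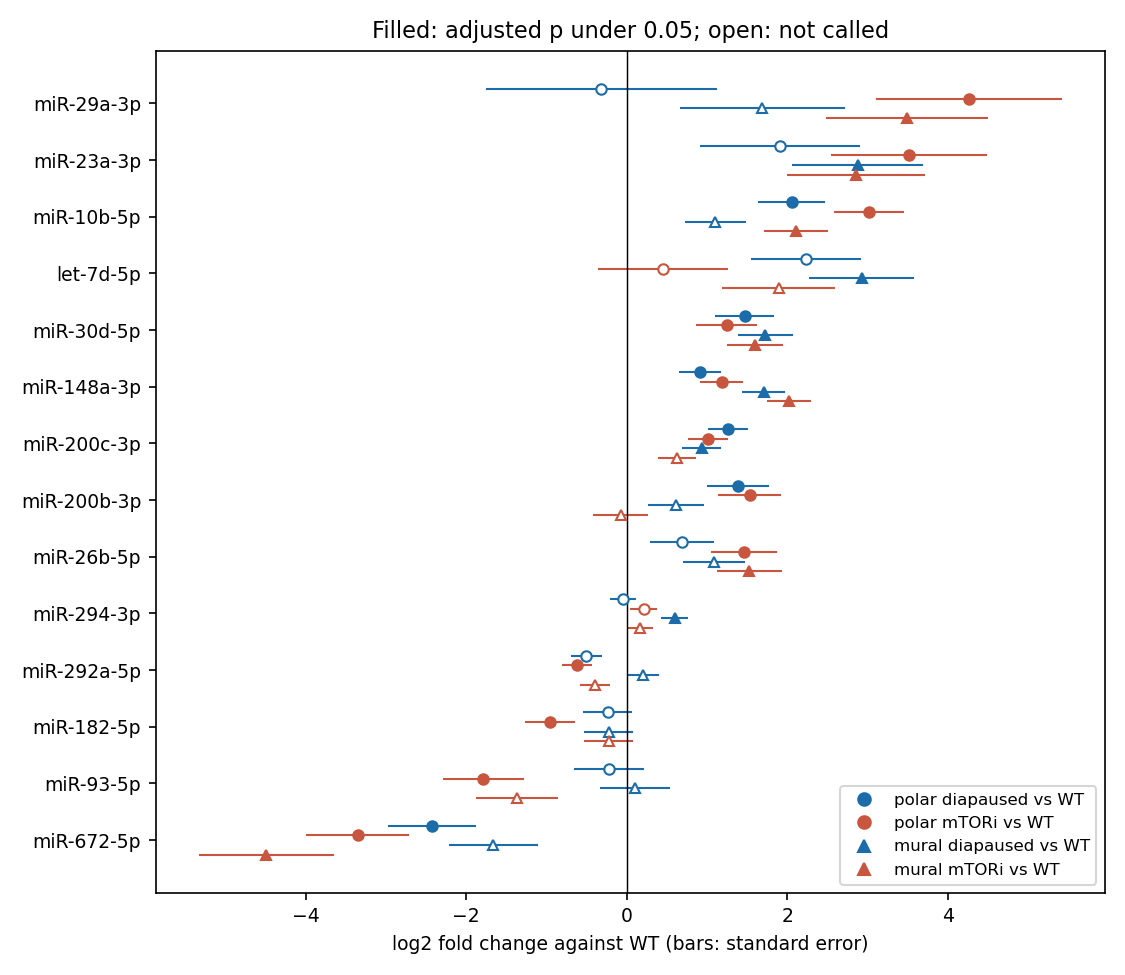
Fitted log2 change against WT (points, with bars of 1 standard error) of 14 miRNAs in polar (circles) and mural (triangles) fragments, with filled symbols for an adjusted p under 0.05. miR-148a-3p and miR-30d-5p are filled in all 4 comparisons, at 0.91 to 2.02 and 1.24 to 1.73.

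In the stromal list only miR-10a-5p and miR-10b-5p were tested, and they made up most of its counts. The list held 1.04% ± 0.167 (SD, n = 2), 4.32% ± 0.836 (n = 3) and 7.35% ± 4.54 (n = 3) of counts in polar WT, diapaused and mTORi libraries. Without polar mTORi replicate 1 (12.2%), the other libraries of that group held 3.29% and 6.502%. In mural fragments the list held 4.16% ± 0.816 (SD, n = 2), 7.56% ± 0.248 (n = 3) and 16.6% ± 0.677 (n = 3). Members other than miR-10a-5p and miR-10b-5p held 0.0898%, 0.0786% and 0.183% in the polar groups and 0.0743%, 0.152% and 0.148% in the mural groups. Leukocyte miRNAs held 0.369% (0.172% and 0.567% in replicates 1 and 2), 0.256% and 0.592% in polar WT, diapaused and mTORi and 0.299%, 0.129% and 0.453% in the mural groups. Most counts of this list were of miR-146b-5p, with 238 in all. miR-155-5p had 23 and miR-142a-3p had 18, of which 14 were in polar WT. Stratified epithelial miRNAs held 0.493%, 0.558% and 9.46% (25.8% in replicate 3) in the polar groups and 0.604%, 0.492% and 1.11% in the mural groups. Erythroid miRNAs held 0.0902% in polar diapaused and 0.130% in polar mTORi (0.275% in replicate 2), and 0.0471% and 0.181% in the mural diapaused and mTORi groups. Endothelial miRNAs reached 0.0729% (polar diapaused), muscle miRNAs 0.0442% (mural diapaused), liver miRNAs 0.0719% (polar mTORi, with 0.183% in replicate 2) and neural miRNAs 0.0170% (mural diapaused). Counts were found for 2 of 18 muscle and 3 of 15 neural names. Names with 2 or more precursors had few counts. For example, the neural miR-219a-5p had 0 beside 7 on its other arms. Low shares of these lists therefore do not show that such cells were absent.

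The calls of both treatments against WT were compared to ask whether natural and induced pausing change the same miRNAs. In polar fragments 7 miRNAs were called in the same direction in both. miR-10b-5p, miR-148a-3p, miR-200b-3p, miR-200c-3p and miR-30d-5p rose, and miR-672-5p and miR-451a fell, the last of them resting on polar WT replicate 2. In mural fragments miR-148a-3p, miR-30d-5p and miR-23a-3p rose in both. Independent lists of these sizes, which leave the shared WT libraries out of account, would share 0.76 rising and 0.20 falling miRNAs in polar, and 0.47 and 0.12 in mural fragments. Simulated unchanged groups that share the WT libraries gave a mean overlap of 0.04 in polar and 0.02 in mural fragments, with a highest value of 1 in 100 sets. Because no change was simulated, this cannot show how many shared calls the common WT libraries give beside real changes. The covariance of the log2 changes of both treatments was 1.25 in polar and 1.02 in mural fragments, against simulated means of 0.411 and 0.329. The correlation across the 102 miRNAs, which are not independent replicates, was 0.500 and 0.620 against simulated 0.647 and 0.583. The 2 WT libraries per part cannot be split, so part of the shared change can come from the shared controls. The polar overlap was 2, 3 and 4 without polar diapaused replicates 2, 1 and 3, 4 without polar mTORi replicate 2 and 3 without polar WT replicate 2, and the mural overlap was 0 without mural WT replicate 2.

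Diapaused and mTORi blastocysts were compared directly to ask where natural and induced pausing differ. In polar fragments miR-29a-3p was lower in diapaused than in mTORi blastocysts, at 224 ± 205.8 against 5760 ± 592 CPM (SD, n = 3 each). miR-28a-3p (in an intron of Lpp) and miR-1981-5p had no count in polar mTORi libraries and were at least 5.17-fold and at least 4.12-fold higher in diapaused ones. miR-5099 was at 9701 ± 3946 CPM (SD, n = 3) in diapaused and 1399 ± 1277 (n = 3) in mTORi fragments. In mural fragments miR-351-5p was 6.55-fold higher in diapaused blastocysts, at 11654 ± 966 against 1782 ± 474 CPM (SD, n = 3 each).

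In polar fragments 16 miRNAs were called, 8 higher and 8 lower in diapaused blastocysts (6 and 10 with RLE factors, 37.5% higher in place of 50%). Far fewer were called in a fit of only the groups compared, as given below. Log2 differences were -4.58 for miR-29a-3p (SE 0.82, edgeR adjusted p = 0.00333), 2.80 for miR-5099 (SE 0.65), -2.62 for miR-5126 (SE 0.87), -2.35 for miR-30e-3p (SE 0.71) and -1.66 for miR-101a-3p (SE 0.42). Count ratios were 17.1 (95% interval 2.97 to 683) for miR-298-5p and 6.29 (95% interval 2.08 to 31.1) for miR-466f-3p. Neither was called without polar mTORi replicate 3 (edgeR adjusted p = 0.103 and 0.0833), where miR-5099 was at 1.93, and without replicate 2 miR-30e-3p was at -1.77 (adjusted p = 0.132). The difference of miR-203-3p was -4.84 (SE 0.96), and -1.78 (SE 0.45, edgeR adjusted p = 0.0146) without polar mTORi replicate 3. The count was 6, 5 and 4 without polar diapaused replicates 1, 2 and 3, and miR-28a-3p, miR-1981-5p, miR-5099, miR-203-3p and miR-29a-3p were called in each fit.

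In mural fragments 1 miRNA was called, miR-351-5p (log2 2.71, SE 0.51, edgeR adjusted p = 0.00613), with 26 at unadjusted p under 0.05. RLE factors gave 1 higher and 4 lower (20% higher in place of 100%) and library size scaling 1 and 3 (25%). The miRNAs next by p were miR-320-3p (log2 -1.62), miR-5126 (log2 -3.70), miR-292a-5p (log2 0.60) and miR-290a-5p (log2 1.29), each with an edgeR adjusted p = 0.0687. Without mural mTORi replicate 2 or 3 edgeR called 0 (18 and 10 at unadjusted p under 0.05), and without replicate 1 it called 3. DESeq2, a fit without a filter, the filter on 10 CPM and a fit of only the groups compared each called more than 1, as given below. The number of differences in mural fragments thus depends on the setting.

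Whether the treatments act differently in polar and mural fragments was tested by the difference of their effects. For diapause edgeR called 0 miRNAs, with 12 at unadjusted p under 0.05, 0 in DESeq2, 0 in edgeR without a filter and 2 with a filter on a mean of at least 10 CPM. The smallest p belonged to miR-101a-3p (log2 difference -2.01), miR-292a-3p (-0.90), miR-294-3p (-0.64), miR-292a-5p (-0.71) and miR-17-5p (-2.11), each with an adjusted p = 0.352. For mTOR inhibition edgeR called 0, with 14 at unadjusted p under 0.05, 1 in DESeq2, 1 in edgeR with RLE factors, 1 with a replicate block, 6 without a filter and 9 with the filter on 10 CPM. The smallest p belonged to miR-351-5p (log2 difference 3.60, edgeR adjusted p = 0.0651), miR-148b-3p (2.79, adjusted p = 0.137), miR-200b-3p (1.61, adjusted p = 0.213), miR-451a (-4.25, adjusted p = 0.226, and -0.44 without polar WT replicate 2) and miR-503-5p (3.27, adjusted p = 0.27, and 0.99 without polar mTORi replicate 1). miR-351-5p was the miRNA called in DESeq2 and with RLE factors, and it was called in edgeR without polar mTORi replicate 3 (adjusted p = 0.031). Without polar WT replicate 2 its log2 difference was 10.37 in place of 3.60, an estimate that rests on 1 polar WT library of 1744 counts. In simulated data this test recovered 26.5% and 22.5% of 4-fold differences, so most differences of that size would be missed. For miR-351-5p the difference between the parts thus depends on the setting, and for the other tested miRNAs a call in 1 part and not in the other is not in itself a difference between the parts.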

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

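Thinning of the libraries and the fit without the miR-290/miR-295 cluster were chosen after seeing the data. Of 264 alternative counts of calls, 164 stayed within 1.5 times the main count and 100 moved. Of 105 calls of named miRNAs, 26 were kept in every alternative, 79 were lost in 1 or more, and 0 reversed. The cause of each move was not tested unless given here. Thinning, which changes depth alone, lowered the count in every contrast with calls except diapaused against mTORi in mural fragments (2 in place of 1).

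With RLE size factors the count was 13 in place of 8 (diapaused against WT, polar), 5 in place of 10 (diapaused, mural), 5 in place of 1 (diapaused against mTORi, mural) and 1 in place of 0 (difference of mTORi effect). Library size alone gave 5 for diapaused against WT in mural and 4 for diapaused against mTORi in mural fragments. RLE moved the median log2 change of all tested miRNAs by -0.11 (diapaused, polar), -0.26 (diapaused, mural), -0.19 (diapaused, mean), 0.14 (polar against mural, diapaused), -0.16 (diapaused against mTORi, mural) and 0.15 (difference of diapause effect). Library size alone moved it by -0.17 (mTORi, polar), -0.31 (diapaused, mural), -0.12 (diapaused, mean), -0.13 (mTORi, mean), 0.46 (polar against mural, diapaused), 0.18 (polar against mural, mean), 0.24 and -0.22 (diapaused against mTORi, polar and mural) and 0.38 (difference of diapause effect).

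Without a filter there were 9 calls for polar against mural in mTORi, 6 for diapaused against mTORi in mural, 6 for the difference of mTORi effect, and overlaps of 3 (polar) and 6 (mural). A filter on a mean of at least 10 CPM gave 6 for diapaused against WT in mural, 9 for polar against mural in mTORi, 7 for diapaused against mTORi in mural, 2 and 9 for the differences of diapause and mTORi effect, and a mural overlap of 6. DESeq2 gave 15 for diapaused against WT in polar, 20, 30 and 10 for polar against mural in WT, diapaused and mTORi, 5 for diapaused against mTORi in mural and 1 for the difference of mTORi effect. A fit of only the groups compared has fewer libraries, and its counts moved both up and down, for which no cause was tested. It gave 2 and 22 for mTORi against WT in polar and mural and 14 for its mean. It gave 7, 29 and 0 in edgeR (8 at unadjusted p under 0.05) for polar against mural in WT, diapaused and mTORi, and 3 and 17 for diapaused against mTORi in polar and mural. Same-numbered polar and mural libraries were taken to share only a number, because not every correlation of their residuals was over 0.1: the diapaused ones were 0.110, -0.011 and 0.364, the mTORi ones 0.112 to 0.183, and the 2 WT libraries per part give 1 value, 0.307. Each mTORi library and 1 of 3 diapaused ones correlated best with its own number, a hint from the data and not the design. A replicate block gave 19 for polar against mural in WT, 5 as before in mTORi, 1 for the difference of mTORi effect and a mural overlap of 5.

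Thinned to 1744 counts, the counts were 3 and 2 for diapaused against WT in polar and mural, 14 and 7 for mTORi, 10 and 19 for the means over parts, 6, 3, 3 and 18 for polar against mural in WT, diapaused, mTORi and on average, 5 and 2 for diapaused against mTORi in polar and mural, and overlaps of 3 and 1. Without the miR-290/miR-295 cluster they were 6 for diapaused against WT in mural, 10 for polar against mural in diapaused and 5 for diapaused against mTORi in mural. For the list tests, 0 of the 4 camera calls held with an estimated correlation, and fry called 21 of 70.

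Leaving out each library in turn gave 2 to 7 (diapaused against WT, polar), 4 to 28 (mTORi, polar), 0 to 6 (diapaused, mural), 6 to 8 (mTORi, mural), 7 to 14 (diapaused, mean), 12 to 36 (mTORi, mean), 4 to 8, 5 to 11, 0 to 6 and 22 to 29 (polar against mural in WT, diapaused, mTORi and on average), 4 to 18 and 0 to 3 (diapaused against mTORi, polar and mural), 0 to 0 and 0 to 1 (differences of diapause and mTORi effect), and overlaps of 2 to 7 (polar) and 0 to 2 (mural). A lone remaining WT library was assumed to vary like the other groups.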

Other observations

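A cluster on chromosome X (66776757 to 66839125), chosen after its values were seen, held 34 mature names, of which 22 were detected. It took 3.61% ± 0.480 (SD, n = 2) of the counts in polar WT, 4.68% ± 1.33 (n = 3) in polar diapaused and 3.66% ± 1.90 (n = 3) in polar mTORi libraries. In mural fragments it took 3.08% ± 1.36 (SD, n = 2), 2.74% ± 0.884 (n = 3) and 3.05% ± 0.787 (n = 3). miR-881-3p (960 counts) and miR-743b-3p (706 counts) were the most abundant members, and no tested member was called by edgeR in any contrast.

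The remaining lists are given as mean shares in polar WT, diapaused and mTORi and then in mural WT, diapaused and mTORi libraries. The miR-30 family took 1.73%, 2.29% and 2.81% (0.971% in polar mTORi replicate 3 and 3.33% and 4.12% in the others), then 1.94%, 3.07% and 4.01%. Its median change in diapause averaged over parts turns sign between scalings. The miR-26 family took 0.966%, 1.56% and 2.19%, then 0.592%, 1.01% and 1.61%. The miR-29 family took 0.0202%, 0.0267% and 0.537%, then 0.0239%, 0.0702% and 0.311%. The miR-183/miR-96/miR-182 cluster took 5.10%, 4.92% and 2.39% (1.03% in polar mTORi replicate 3 and 2.42% and 3.71% in the others), then 4.43%, 3.12% and 3.18%. Both tested members, miR-182-5p and miR-183-5p, were called lower with mTOR inhibition on average, miR-182-5p not without polar mTORi replicate 3. The miR-99/miR-100 and miR-125 families took 1.40%, 1.81% and 1.44%, then 2.60%, 1.44% and 0.925%. The Sfmbt2 cluster, known from trophoblast, took 2.22%, 3.25% and 1.49%, then 2.64%, 1.89% and 1.59%. The miR-15/miR-16 family took 0.398% (0.229% and 0.567%), 0.818% and 1.27%, then 2.70%, 2.76% and 2.57%. Its list includes miR-322-5p and miR-322-3p of the miR-322/miR-503 cluster, at 19801.7 and 4860.7 CPM in mural WT. There miR-15a-5p and miR-15b-5p were at 1418.6 and 795.4 CPM, so the mural shares are mostly those of miR-322. The miR-23/miR-27/miR-24 clusters took 0.255%, 0.503% and 0.935% (2.03% in polar mTORi replicate 3 and 0.321% and 0.457% in the others), then 0.285%, 0.571% and 0.517%. The miR-221/miR-222 cluster took 0.0590%, 0.0323% and 0.490% (1.23% in polar mTORi replicate 3 and 0.0458% and 0.196% in the others), then 0.0783%, 0.0364% and 0.112% (0.258% in mural mTORi replicate 3). The miR-34/miR-449 family stayed at or under 0.0956% and the miR-181 family at or under 0.0267% in every group. miR-181a-5p, which has 2 precursors, had 0 counts beside 3 on its other arms. The miR-181 share, and those of the miR-29, miR-30 and miR-125 families, may therefore leave out such members and be too low.

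Tests of miR-203-3p, of miR-148a-3p, of names with several precursors, of thinned libraries and without the miR-290/miR-295 cluster were chosen only after results were seen, and the other tests here before. miR-203-3p rose with mTOR inhibition on average, and RNA of stratified epithelial cells in polar mTORi replicate 3 could raise it. That library alone does not account for the rise, since without it the mean over parts was still called, at 1.40 (edgeR adjusted p = 0.00705). Whether it rises in every mTORi library stays open, since its lowest share there (0.425%, 13 counts) was 0.926 times the highest in a WT library (0.459%, 8 counts), with a 95% interval of 0.356 to 2.58. In replicate 3 miR-205-5p was 16.7 times its share in the other polar mTORi libraries (95% interval 9.66 to 31.2), beside 23.3 times for miR-203-3p, which is consistent with RNA of stratified epithelial cells in that library.

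Mature names with 2 or more precursors had few counts: 2.47% of them reached 20 counts, against 9.29% of names with 1 precursor. A candidate explanation is that reads matching several loci were left out of the deposited counts. Of 13 such names whose other arm is specific to a locus, 10 had fewer counts than that arm and 2 had more. The explanation does not reach the 2 names with the most counts, miR-92a-3p (713) and miR-466f-3p (191).

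In polar fragments 5 miRNAs rose in both diapaused and mTORi blastocysts, and more trophectoderm in those fragments could raise miRNAs that are high in mural tissue. The explanation cannot be told apart for the set, because the 5 other mural-high miRNAs are all of the miR-322/miR-503 cluster, spread from 0.029 to 1.62 (median 0.482) in diapaused and from -0.139 to 2.23 (median 0.976) in mTORi fragments, against 1.39 and 1.24 for the set, and 2 of them fell in mural mTORi fragments. Of the set, 3 of 5 were not called mural-high in WT (miR-30d-5p and miR-200c-3p of these were lower in polar fragments on average over treatments), its medians in mural fragments were 1.10 and 1.59, and the miR-302/miR-367 share, at 0.282% in polar WT, was 0.0480% and 0.0305%. For miR-148a-3p, polar fragments held more than mural ones, by 0.56 (SE 0.22, edgeR adjusted p = 0.0928) in diapaused and 0.51 (SE 0.23) in mTORi blastocysts. These differences, which were not called, lean against added mural trophectoderm. The level in polar trophectoderm was not measured, so the explanation is not excluded. Thinning cannot decide on depth, because it leaves the expected share of each miRNA unchanged. The medians of the set with thinned libraries, 1.304 and 1.179, therefore had to stay near those of the full libraries. Counts taken by the miR-290/miR-295 cluster are argued against, with medians of 1.226 and 1.132 without it. The pausing itself and the differing stage and culture of the WT blastocysts stay open, as untested.

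If every library is independent, chance in the grouping of libraries is argued against for the means over parts and for polar against mural on average. The splits treated same-numbered polar and mural libraries as unrelated, and the labels do not say whether they share embryos. If they do, fewer splits apply, so chance is not excluded. Of the 100 splits run in each case (for polar against mural a draw from 1200), 1, the real one, gave as many calls: 19 against at most 4 for diapaused, 33 against at most 15 for mTORi, and 28 against at most 24 for polar against mural. For polar against mural in diapaused (19 calls, highest other split 0) and in mTORi (5, highest other 1), and for diapaused against mTORi in polar (16, highest other 2) and in mural fragments (1, highest other 0), the 10 splits are too few for a share under 0.05.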
